A study of Mus musculus with 6 samples.

How the data were processed

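Total RNA of 6 mouse samples was sequenced, 1 library per group: bone marrow cells (BM), macrophages grown from marrow with M-CSF (M-BMDM), the same cells with interleukin-6 (IL6) for 3 h or 24 h, macrophages grown with GM-CSF (GM-BMDM), and these with IL6 for 3 h. Per the labels, the mice were C57BL/6, 8 weeks old, and the cultures lasted 7 days.

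The deposited table held estimated counts per gene, which need not be whole numbers. Between 24.7% and 27.7% of the values above 0 were not whole in each library. The submitters' processing notes name HISAT2, StringTie and DESeq2, with no version, and the GRCm38 build; the order and the settings are not given in the sources used here, and neither is whether counting used strand. The expected counts were rounded to whole numbers before any test. Of 56278 rows, 742 had no gene name; they held from 0.240% of the counts (GM-BMDM with IL6 for 3 h) to 0.522% (BM) and were left out of library sizes and tests. All 55536 named rows matched a gene identifier of the GENCODE M21 annotation, which gave chromosome positions, and 55509 had the same symbol there; the others had symbols turned into dates and took the annotation's symbol. 237 named rows shared a symbol with another row. Genes were analysed when at least 1 library reached a CPM of 1, where CPM is the count scaled to a common library size, which left 14719 genes. Library totals ran from 18567482 to 24196082 counts.

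Counts were scaled by TMM (edgeR 4.0.16, R 4.3.3). Comparisons of 2 kinds were made, both set before the data were examined. For each pair of libraries, the ratio of scaled counts was given with its exact 95% Clopper-Pearson interval from the conditional binomial distribution. A gene was counted as higher or lower when the ratio was at least 2-fold, its interval excluded 1 and the higher library had at least 5 scaled CPM. Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per group these values describe 2 libraries and have no replicate check. Where a library had 0 counts, the fold is a bound computed against 3 counts in that library.

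The second kind was edgeR's quasi-likelihood test in 1 fit of all 6 libraries, with terms for cell type, IL6 for 3 h and IL6 for 24 h, and Benjamini-Hochberg adjustment at 0.05. This fit leaves 1 residual degree of freedom, the difference between the 3 h responses of the 2 macrophage types, so the spread was shared across genes (biological coefficient of variation 6.45%, prior degrees of freedom 502.2). Contrasts with BM or with the 24 h library rest on a lone library that is assumed to vary as little as the 3 h libraries did. The p-values rest on the spread between the 3 h responses of the 2 macrophage types. This spread may be technical, since nothing in the labels says that libraries came from separate cultures or animals. Spread between an M-CSF and a GM-CSF culture was not measured, and the fit counts it as a difference of cell type. A further fit treated both IL6 times as 1 level within each macrophage type, to test whether the IL6 response differed between the types (coefficient of variation 44.6%).

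34 gene lists fixed beforehand were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. The estimate comes from the 1 residual degree of freedom, so few lists could pass with it, whatever their genes did. The preset correlation was not measured in these data. For each pair of libraries, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. List medians use the prior count of 2, while the ratios of single genes use none, except those of the genes whose 3 h differences ran in opposite directions in the 2 macrophage types. Named genes followed a fixed rule. For each pair these were the 10 highest and 10 lowest ratios among counted genes with at least 10 scaled CPM, leaving out predicted, clone-based and antigen receptor names. For each test they were the 10 genes with the lowest adjusted p per direction that moved the same way in both pairs. Up to 4 counted members per list were added, and Socs3, Stat3, Il6ra, Il6st, Csf1r, Csf2ra and Csf2rb were named in every comparison. Genes outside the rule are marked as chosen after their values were seen.

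The alternatives were DESeq2 size factors, total counts, upper-quartile factors, other limits of CPM and fold, no counting interval, no filter, a CPM filter of 5, the DESeq2 1.42.0 Wald test, limma-voom and smaller or simpler designs. Some were added after the data were seen: a fixed coefficient of variation of 0.2, the 3 h library as reference for 24 h, and removal of each library's trend with GC content. The steps were tested on simulated data, drawn from the means and spread of the same fit. The shares below thus assume that a lone library, such as that at 24 h, varied as little as the 3 h libraries. They are no error rates of the tests on the real counts. For the test of IL6 at 3 h on 14456 simulated genes, 91.0% of 2-fold and 73.1% of 1.5-fold changes were recovered, and 7.45% of calls were false. For IL6 at 24 h (14444 genes) 79.1% of 2-fold changes were recovered and 9.09% of calls were false. For GM-BMDM against M-BMDM (14257 genes) these shares were 82.1% and 1.81%. In 20 simulated pairs without any difference (14719 genes), the size rule counted a median of 9 and at most 13 genes for the M-BMDM pair at 3 h, and a median of 14 and at most 29 for the GM-BMDM pair. The table held no column of another sample. Versions of the other tools were Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.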

Results

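Gene expression was measured by RNA sequencing in mouse bone marrow cells and in macrophages grown from marrow for 7 days. The macrophages were grown with M-CSF (M-BMDM) or with GM-CSF (GM-BMDM), and some were given interleukin-6 (IL6). There were 6 groups: uncultured marrow (BM), each macrophage type without IL6, each type after 3 h of IL6, and M-BMDM after 24 h of it. Each group had 1 library and no replicate, so intervals given with ratios cover counting error only. The libraries held 21597786 counts (BM), 18567482 (M-BMDM), 22694865 (the same after 3 h of IL6), 21848228 (after 24 h), 24196082 (GM-BMDM) and 20283616 (GM-BMDM after 3 h). Of 55536 named genes, 25679 had a count in any library and 14719 were analysed further.

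The libraries differed in composition. Haemoglobin transcripts, from red cell precursors, made up 8.77% of the counts in BM and at most 0.001% in the cultures, and Hba-a2, an alpha globin, was the top gene of BM with 3.12%. Lyz2, which encodes the lysozyme of myeloid cells, was the top gene of M-BMDM with 2.62% and of GM-BMDM with 3.99%. Transcripts of the mitochondrial genome made up 1.70% in BM, 2.06% in M-BMDM and 3.15% in GM-BMDM. The receptor parts through which IL6 acts were expressed in all libraries. Il6ra, the IL6 receptor alpha chain (chromosome 3, 89864059 to 89913196, GRCm38), had 59.1 scaled counts (CPM) in M-BMDM and 36.3 in GM-BMDM, and Il6st, the shared chain gp130 (chromosome 13, 112464070 to 112510086), had 97.6 and 118. Socs3, the feedback inhibitor of IL6 signalling (chromosome 11, 117966079 to 117970047), had 102 CPM in M-BMDM, 99.4 after 3 h and 7.60 after 24 h of IL6.

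**Figure D1:**
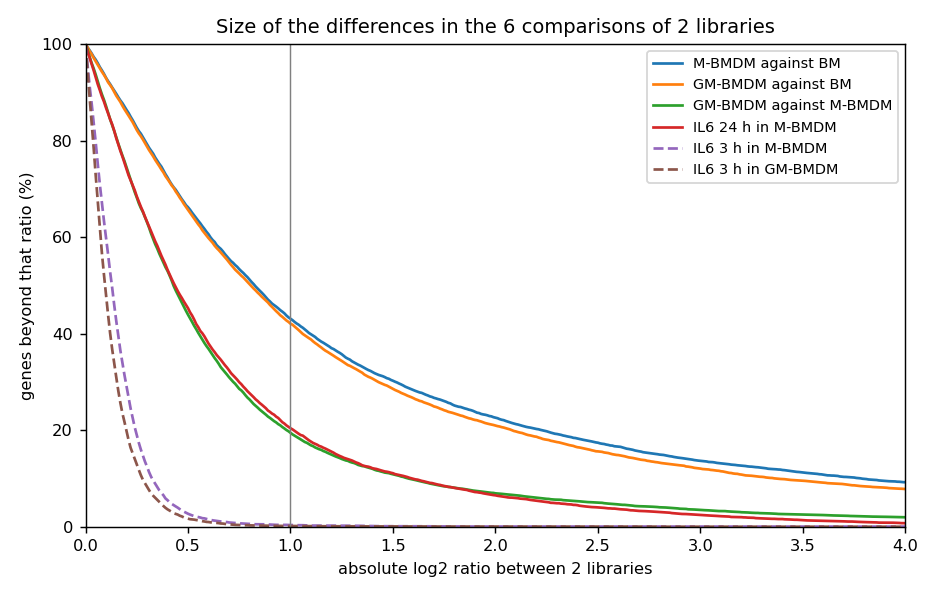
Ratios of single genes between pairs of libraries. The IL6 pairs at 3 h are narrow beside the pair at 24 h and the pairs between cell types.

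Marrow grown with M-CSF lost the blood cell lineages of the marrow and gained macrophage genes. Granule proteins of neutrophils, globins, and B cell genes were almost absent after 7 days. Core macrophage genes, lysosomal genes and sterol synthesis genes were mostly higher. Cell cycle genes were lower in the culture than in marrow. Of 11245 genes with at least 5 CPM in either library, 2260 were at least 2-fold higher in M-BMDM and 2587 at least 2-fold lower.

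Among the genes with the highest ratios in M-BMDM were Fxyd2, a regulator of the sodium pump (log2 ratio 12.08, 95% interval 9.60 to 17.38), Arhgap22, which switches off Rac (11.26, 8.78 to 16.56), Npy, the peptide neuropeptide Y (10.90, 9.05 to 13.95), and Gpnmb, a glycoprotein of lysosomes and the cell surface (10.47, 10.20 to 10.75). The chemoattractants of monocytes Ccl7 (10.12, 8.58 to 12.40) and Ccl2 (8.61, 7.98 to 9.32) were higher too, as were Saa3, an acute phase protein (10.03, 8.18 to 13.08), the elastase Mmp12 (8.70, 8.16 to 9.30) and the aminopeptidase Anpep (8.58). Gng4, a G protein subunit without a count in BM, was at least 232.3-fold higher. Csf1r, the M-CSF receptor (chromosome 18, 61100598 to 61132149), was 18.9-fold higher (log2 4.24, 4.19 to 4.28), Socs3 was higher (2.72, 2.55 to 2.88), and Csf2rb, the signalling chain of the GM-CSF receptor, was higher by 1.69. Stat3, the transcription factor of IL6 signalling (-0.15), Il6ra (-0.75), Il6st (0.56) and Csf2ra, the ligand-binding chain for GM-CSF (0.42), stayed below 2-fold.

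Of 36 core macrophage genes, 31 were higher, none was lower and 5 were neither, with a median log2 ratio of 3.50. They included C3ar1, a complement receptor (8.17), Cd14, which binds endotoxin (7.68), and Trem2, a lipid receptor (6.95). Lysosomal genes were higher for 26 and lower for 3 of 34, among them the proteases Ctsl (4.69), Ctss (4.22) and Ctsd (4.21). Sterol synthesis was higher for 16 of 24 genes and lower for 0, led by Sqle (3.57), Msmo1 (3.13), both enzymes of the pathway, and Insig1, its feedback regulator (3.10). Pro-inflammatory genes were higher for 22 and lower for 3 of 31, with Acod1, the enzyme that makes itaconate (7.98, 7.75 to 8.22). Interferon-stimulated genes were higher for 25 of 39 and lower for 0, including Cxcl10, a T cell attractant (6.14), and the antiviral genes Ifit3 (3.37) and Ifit1 (3.22). Complement and apolipoprotein genes were higher for 8 of 11 and lower for 1, with C1qb (4.76) and the lipid carrier Apoe (3.91). STAT3 target genes were higher for 18 and lower for 7 of 40, with Tgm2, a transglutaminase, at 6.23, and glycolysis and hypoxia genes were higher for 15 and lower for 1 of 26, with the glucose carrier Slc2a1 at 4.13.

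Most of the largest drops of single genes concerned granulocytes, although the erythroid list had a lower median (-10.2) than mature neutrophil genes (-9.21). S100a9, a calcium-binding protein of neutrophils (-17.65, -22.96 to -15.17), Ltf, lactoferrin (-15.76, -18.81 to -13.91), Ngp, a granule protein (-14.50, -15.81 to -13.46), Camp, an antimicrobial peptide (-14.19, -17.23 to -12.33), and Mpo, the myeloperoxidase (-14.97, -20.27 to -12.49), were lower in M-BMDM. Prg2 (-15.52, -20.82 to -13.04) and Epx (-13.37, -18.68 to -10.90), both of eosinophil granules, were lower as well. Retnlg, a resistin-like peptide of neutrophils, was at least 6571-fold lower, Elane, the neutrophil elastase, at least 3710-fold, and Prtn3, proteinase 3, at least 2449-fold. Mature neutrophil genes were lower for 22 of 25 and higher for 0, and precursor granule genes were lower for 11 of 13. All 26 erythroid genes were lower, such as Hbb-bt (-13.14), Hba-a1 (-13.10, -13.62 to -12.62) and the anion exchanger Slc4a1 (-14.47, -17.52 to -12.62). B lineage genes were lower for 21 of 24, with Cd79a, part of the B cell receptor, at -10.91 (-13.96 to -9.06). Stem and progenitor genes were lower for 15 of 19, with the transcription factor Myb at -10.79 (-13.84 to -8.94), and megakaryocyte genes for 12 of 15, with the platelet tubulin Tubb1 at least 327.7-fold lower. Stromal genes were lower for 16 of 23, with the chemokine Cxcl12 at -9.73. Proliferation genes were lower for 32 of 34 and higher for 0 (median -2.78), with the replication genes Cdc6 (-5.37) and Mcm7 (-4.91) and the nucleotide enzymes Rrm2 (-4.22) and Tyms (-4.04).

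In the fit of all 6 libraries, 5022 genes rose and 5575 fell in M-BMDM against BM. Acod1 rose (log2 7.95, standard error 0.175, adjusted p = 2.5e-177), as did Gpnmb (10.51, 0.238, 1.1e-172). Chil3, a chitinase-like protein of myeloid cells (chromosome 3, 106147554 to 106167564), fell (-13.20, 0.201, 8.0e-245), as did S100a8 (-11.61, 0.187, 4.1e-234) and Ngp (-14.58, 0.237, 1.6e-232). These p-values rest on the lone BM library having as little spread as the 3 h libraries, so their size was not checked by any replicate. Scaling by total counts would move the median ratio of genes by -0.17.

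Marrow grown with GM-CSF lost the same lineages and gained macrophage and lysosomal genes. Genes of alveolar macrophages and of alternative activation were higher as well. Interferon genes were, in contrast with the M-CSF culture, mostly lower or little different. Of 11367 genes with at least 5 CPM, 2250 were at least 2-fold higher in GM-BMDM than in BM and 2534 lower. With total counts these were 1691 and 3450, a median shift of -0.33.

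Rbp4, the retinol carrier, had no count in BM and was at least 7904-fold higher in GM-BMDM. Ccn3, a matricellular protein, was at least 2714-fold higher and Ccl17, a chemokine for T cells, at least 1488-fold. Mmp12 was higher by 13.31 (12.77 to 13.92), Spint1, a protease inhibitor, by 12.34 (9.86 to 17.64), Gpnmb by 11.92 (11.65 to 12.21), Cxcl3, a neutrophil attractant, by 11.17 (8.69 to 16.48), Npy by 10.86 (9.01 to 13.91), Spp1, osteopontin, by 9.81 (9.68 to 9.95), and Ahnak2, a scaffold protein, by 9.79. The receptor chains for GM-CSF were higher, Csf2rb 14.3-fold (3.84) and Csf2ra by 1.41. Csf1r (2.64) and Socs3 (3.20) were higher, Il6ra was lower (-1.46), and Stat3 (-0.32) and Il6st (0.84) were neither.

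Core macrophage genes were higher for 32 of 36 and lower for 1. Lysosomal genes were higher for 32 of 34 and lower for 0 (median 2.88), including Ctsd (6.06), Ctsl (5.76) and Ctss (5.43), and sterol synthesis genes for 23 of 24, including Cyp51 (3.73), Sqle (3.49) and Hmgcs1 (3.33). Genes of alveolar macrophages were higher for 17 and lower for 3 of 21, such as the proton pump part Atp6v0d2 (8.90), the surface protein Plet1 (8.85, 7.30 to 11.13), the fusion protein Dcstamp (7.89) and the lipase Lpl (5.83). Alternative activation genes were higher for 16 and lower for 5 of 27, with Arg1, arginase (9.26), and Ccl22, a chemokine (8.04). Mitochondrially encoded genes were higher for 8 of 12, and nuclear genes of oxidative phosphorylation for 6 of 32, with Cox5a at 1.25, both with 0 lower. Interferon-stimulated genes were higher for 5 and lower for 10 of 39, with the antiviral genes Rsad2 (-3.18) and Cmpk2 (-3.09) and the regulator Irf7 (-3.05).

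Slc4a1 was at least 17690-fold lower in GM-BMDM, Retnlg at least 7672-fold and Epx at least 4131-fold. Camp (-15.41, -20.71 to -12.93), Mpo (-15.19, -20.50 to -12.72), the haem enzyme Alas2 (-14.80, -20.10 to -12.32), Prg2 (-14.74, -17.79 to -12.89), Hba-a1 (-14.21), Hba-a2 (-13.84), Hbb-bs (-13.72) and Hbb-bt (-13.48) were lower too. All 26 erythroid genes, 20 of 25 mature neutrophil genes and 20 of 24 B lineage genes were lower. Neutrophil transcripts were among them at values such as -11.34 for Elane, -11.25 for S100a9 and -11.70 for Ltf. Proliferation genes were lower for 32 of 34 (median -2.30), with Cdc6 (-3.72), the proliferation marker Mki67 (-3.13) and the spindle motor Kif11 (-3.12).

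By the test, 4852 genes rose and 5701 fell in GM-BMDM against BM, or 3544 and 7079 with total counts, and the DESeq2 test called 6877 in either direction. Mmp12 rose (13.33, standard error 0.257, adjusted p = 2.8e-201), while Mmp9, the gelatinase of neutrophils (-8.71, 0.145, 3.8e-227), and Hba-a2 (-13.74, 0.235, 6.0e-223) fell. The 2 cultures shared 1443 genes higher than BM (345 if independent) and 2049 lower (445 if independent), while 19 and 39 differed in opposite directions. The ratios of the 2 cultures correlated at 0.86 with a covariance of 4.4, against 0.489 and 0.0197 in simulations in which only the BM library was shared, and the simulations gave 8.85 shared calls. Part of the excess may come from the shared BM library.

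The cultures with the 2 growth factors differed in transcripts of many immune genes. No function was measured, and these values cannot tell changed macrophages from a different mix of cells. GM-BMDM had more transcripts of alternative activation, MHC class II, dendritic cells, alveolar macrophages and lysosomes. M-BMDM had more interferon-stimulated, complement and glycolytic transcripts. Of 10495 genes with at least 5 CPM, 1134 were at least 2-fold higher and 907 lower in GM-BMDM than in M-BMDM. With total counts these were 904 and 1191, a median shift of -0.16.

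Ccn3 was at least 2080-fold higher in GM-BMDM, and the ribonucleases Ear6 and Rnase2a were at least 459.4-fold and 155.9-fold higher. Plet1 was at least 353.2-fold higher. Chil3 had 983 CPM in GM-BMDM and 0.215 in M-BMDM, a log2 ratio of 12.16 (10.80 to 14.03). Rbp4 (11.15, 10.17 to 12.36), Ccl17 (10.74, 8.89 to 13.79), the pentraxin Ptx3 (10.34, 7.86 to 15.65), the zinc carrier Slc39a2 (10.10, 7.62 to 15.41) and Ear2 (9.22, 7.37 to 12.27) were higher. Cish, an inhibitor induced by STAT5 signalling, was higher by 7.49 (6.83 to 8.25), Socs2, from the same family, by 4.71, and Csf2rb by 2.15. Hmga2, a chromatin protein (-6.84), Folr2, a folate receptor (-7.72, -10.77 to -5.86), Col18a1, a collagen (-6.79), Cd300ld4, a receptor (-6.34), Cx3cr1, the fractalkine receptor (-6.23, -6.52 to -5.96), Pcp4l1, a calmodulin-binding protein (-6.19), Adra1a, an adrenergic receptor (-6.07), Abcb4, a phospholipid carrier (-5.95), Fosl1, a transcription factor (-5.81), and Clec4a1, a lectin (-5.72), were lower. Csf1r was lower (-1.60), and Csf2ra (0.98), Socs3 (0.48), Stat3 (-0.17), Il6ra (-0.70) and Il6st (0.28) were neither.

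Interferon-stimulated genes were lower in GM-BMDM for 30 of 39 and higher for 0 (median -2.19), including Ifit3b (-4.77), Ifit3 (-4.32), Mx2 (-3.34) and Irf7 (-3.28). In the test, 37 of them fell and 0 rose. The list test gave adjusted p = 1.4e-13 with a preset correlation and adjusted p = 0.583 with an estimated correlation. Complement and apolipoprotein genes were lower for 6 of 11 and higher for 1, with Apoe (-3.23), C1qc (-2.36) and C1qb (-2.34), adjusted p = 0.0245 and, with an estimated correlation, 0.583. Glycolysis and hypoxia genes were lower for 8 of 26, with Egln3, an oxygen sensor (-3.37), and Vegfa, a vessel growth factor (-1.95), adjusted p = 0.000974 and, with an estimated correlation, 0.587. Pro-inflammatory genes were lower for 15 and higher for 6 of 31, with Ccl7 at -3.63 and Cd38, an NAD enzyme, at 5.26. Core macrophage genes went both ways, 8 higher and 10 lower, with Mertk, a receptor for dead cells, at 3.21, and C5ar1, a complement receptor, at -3.75.

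Alternative activation genes were higher in GM-BMDM for 13 and lower for 3 of 27, with Mgl2, a lectin, at 6.00 and Pdcd1lg2, a ligand of PD-1, at least 142.5-fold higher. MHC class II genes were higher for 6 of 14 and lower for 0, with H2-DMb2 (3.78) and H2-DMa (2.18), which load peptides, the regulator Ciita (1.37), and H2-Aa (1.28). Dendritic cell genes were higher for 11 of 20 and lower for 1, with Clec9a, a receptor for dead cells (7.19, 5.33 to 10.24), Ccr7, a homing receptor (6.56), and the integrin Itgax (5.25). Alveolar macrophage genes were higher for 14 of 21 and lower for 1, with the anhydrase Car4 (6.89, 5.34 to 9.18). Lysosomal genes were higher for 11 and lower for 1 of 34, with Atp6v0d2 (4.87), the phosphatase Acp5 (4.17) and the protease Ctsk (3.68). Sterol synthesis genes were higher for 8 of 24, with Dhcr7 (3.08) and Mvd (2.57), and proliferation genes for 7 of 34, with Mcm7 (2.10) and Rrm2 (1.79). Adjusted p was 0.00263 for alternative activation, 0.000131 for MHC class II, 7.2e-05 for dendritic cell, 8.6e-06 for alveolar macrophage and lysosomal, 0.000975 for sterol synthesis and 9.2e-05 for proliferation genes. Each of these became adjusted p = 0.583 with an estimated correlation. Marker lists of other cell types rose in the same test: megakaryocyte and platelet genes (12 rose, 0 fell, adjusted p = 0.000227), stem and progenitor genes (11 and 1, 0.00642), mature neutrophil genes (14 and 3, 0.00896) and neutrophil precursor genes (7 and 1, 0.0251), each with adjusted p = 0.583 with an estimated correlation. Of 34 lists, 19 passed with the preset correlation and 0 with the estimated one, where 1 residual degree of freedom left little power.

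In the test, which compares the types in 2 pairs of libraries, 4259 genes rose and 4028 fell in GM-BMDM, and 4230 and 3999 moved the same way in both pairs. The labels do not say whether a 3 h library and its control came from separate cultures, so the pairs may not be replicates. The p-values below thus do not cover spread between cultures. With total counts 3439 rose and 4912 fell, and in either direction the DESeq2 test called 4969 genes and a fixed coefficient of variation of 0.2 called 4359. Rbp4 rose (11.41, standard error 0.166, adjusted p = 4.1e-253), as did Chil3 (11.98, 0.184, 9.1e-244), Fstl1, a secreted glycoprotein (6.81, 0.116, 3.9e-223), Inhba, the activin A subunit (6.54, 0.117, 4.0e-214), and Itgax (5.28, 0.102, 1.2e-199). Cx3cr1 (-6.35, 0.116, 3.7e-210), Col18a1 (-7.10, 0.142, 1.1e-194) and Ccnd1, cyclin D1 (-5.02, 0.102, 9.6e-191), fell. Stab1, a scavenger receptor (-4.39), Jag1, a Notch ligand (-4.43), and Cxcl14, a chemokine (-4.75), fell too. By the same test, 18 alternative activation genes rose and 5 fell, 29 lysosomal genes rose and 2 fell, and 26 proliferation genes rose and 2 fell, or 27 and 2 when adjusted over the list alone.

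**Figure D2:**
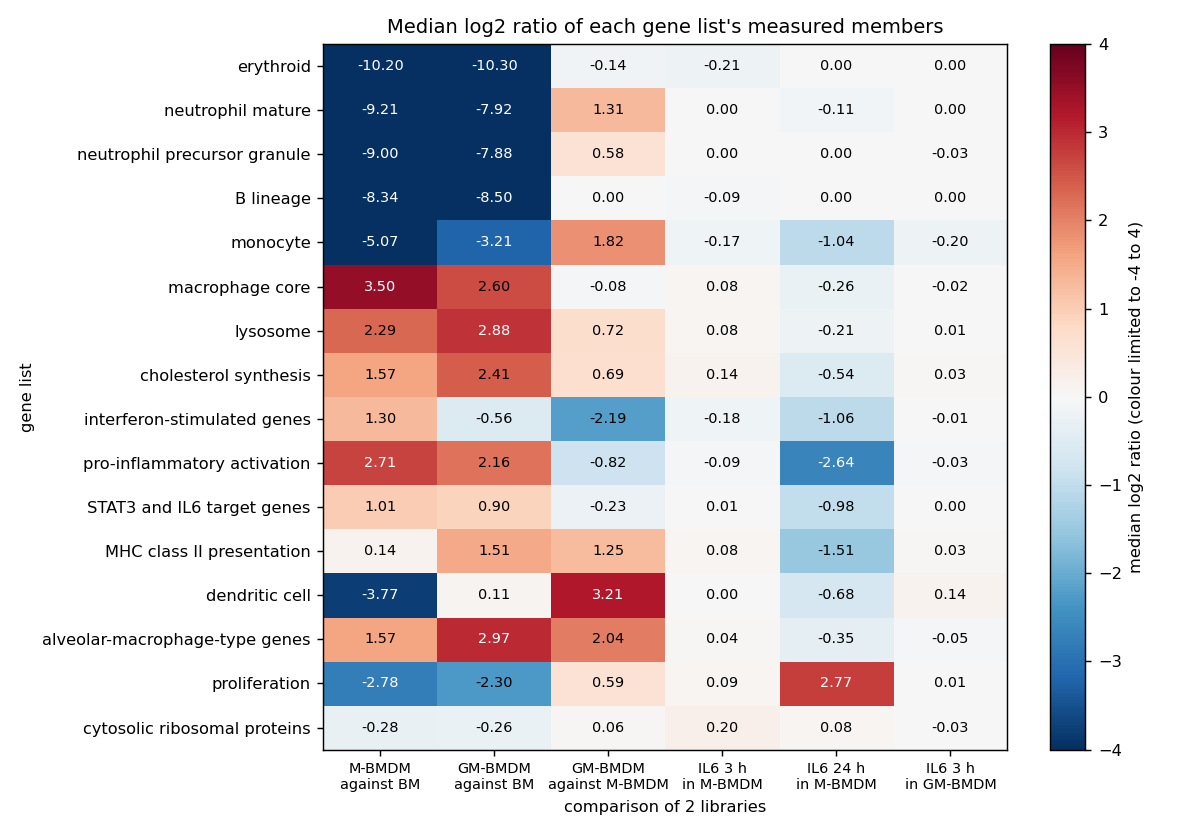
Gene lists in each pair of libraries, as the median ratio of their genes. The largest IL6 differences are those at 24 h, in the proliferation and pro-inflammatory lists.

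IL6 for 3 h left nearly all genes within 2-fold in both macrophage types. None of the STAT3 target genes, Socs3 among them, met the 2-fold limits for a difference between libraries, and in the joint test only Cebpb fell. Among the genes that differed by the limits or by the joint test were mitochondrial transcripts, nuclear noncoding RNAs and genes with near-identical copies. The 2 macrophage types had few differences in common. In M-BMDM, 9 of 9937 genes were at least 2-fold higher and 27 lower, and in GM-BMDM 6 of 10255 were higher and 11 lower. Simulated pairs without any difference gave at most 13 such genes for M-BMDM, and a median of 14 and at most 29 for GM-BMDM. The number of 17 genes in GM-BMDM was within its simulated range, which says nothing about single genes. The simulated spread came from the difference between these same 3 h responses. The simulations therefore cannot tell a response from noise in either type.

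In M-BMDM, Socs3 had a log2 ratio of -0.03 (-0.12 to 0.06), Stat3 0.12, Il6ra 0.04, Il6st -0.02, Csf1r 0.07, Csf2ra 0.00 and Csf2rb 0.09. In GM-BMDM, Socs3 had -0.01 (-0.08 to 0.07), Stat3 0.12, Il6ra 0.08, Il6st 0.22, Csf1r -0.02, Csf2ra -0.22 and Csf2rb 0.05. None of 40 STAT3 target genes was counted in either type, and the list medians of 0.00571 and -0.000859 lay among those of random lists (-0.0552 to 0.0851 and -0.0305 to 0.0615). In M-BMDM, the nucleotide enzyme Entpd4 was higher (1.72, 1.51 to 1.94) and its near-identical copy Entpd4b lower (-1.52). The pseudogene Rps13-ps2 (-2.37), the cytochrome oxidase subunit mt-Co3 (-1.35, -1.41 to -1.28), the collagen Col1a1 (-1.07) and 3 genes of the placenta, the hormone Prl3b1 (-1.37), the glycoprotein Psg21 (-1.30) and Tpbpa (-1.06), were lower. In GM-BMDM, mt-Co2, another oxidase subunit, was lower (-1.32, -1.40 to -1.23). The ratios of the 2 types correlated at 0.0313 over 10616 genes, with 0 genes higher (0.00367 expected if independent) and 2 lower (0.0202 expected) in both.

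In the joint test, 26 genes rose and 116 fell with IL6 at 3 h, and 18 and 112 of them moved the same way in both types. The test combines the 3 h responses of both types, so it favours genes that moved the same way in both. These numbers therefore cannot show that the types shared a response. Without such selection, the ratios of the types correlated at 0.0313 over 10616 genes. In place of these 142 genes, the DESeq2 test called 3, total counts 81 and a fixed coefficient of variation of 0.2 called 38, with 19 rising and 19 falling. A fit of the 4 libraries without and with 3 h of IL6 called 136 genes, and 27 after removal of each library's trend with GC content. The 110 genes no longer called had a median log2 change of 0.438 before and 0.342 after, in the direction first called, with median standard errors of 0.108 and 0.103. Of the annotated gene Fam220a, a nuclear protein that binds STAT3, 1 locus rose (0.80, standard error 0.124, adjusted p = 6.9e-07) and an overlapping locus fell (-3.92, 0.275, 7.3e-35), at chromosome 5, 143548706 to 143564531. Folr2 (0.64, 0.153, 0.00869), Bmf, a death-inducing protein (0.50, 0.125, 0.0131), and mt-Nd3, a complex I subunit (0.46, 0.0879, 0.000172), rose. The 10 rises of lowest adjusted p also included Lrch4 and the predicted genes Gm29609, Gm44965, Gm5345, Gm49369 and Gm20536. Among the 10 such falls were the predicted gene Gm47123 and the pseudogene Rps13-ps2. mt-Co2 (-1.05, 0.0847, 3.0e-27), mt-Co3 (-0.77, 0.0882, 2.8e-13), and the nuclear noncoding RNAs Malat1 (-0.55, 0.0849, 6.6e-07) and Neat1 (-0.52, 0.0880, 1.5e-05) fell. Prpf38b (-0.52, 0.0888, 1.5e-05), Luc7l2 (-0.47, 0.0847, 7.1e-05) and Hnrnph1 (-0.44, 0.0829, 0.000155), which each encode a splicing factor, fell as well, but splicing genes were not tested as a list. Of STAT3 target genes, only Cebpb, a transcription factor, fell (-0.33, adjusted p = 0.0181) and 0 rose. List members that moved, chosen like Cebpb after their values were seen, were Ifit2 (-0.46, 0.00929) and Mx1 (-0.42, 0.0480), both antiviral, Egln3 (0.82, 0.0287), mt-Nd4l, a complex I subunit (-0.50, 0.000850), Cenpf, a kinetochore protein (-0.41, 0.0361), and Col1a1 (-0.70, 0.00445).

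STAT3 target genes as a list gave adjusted p = 0.717 with a preset correlation at 3 h, and adjusted p = 0.827 with an estimated correlation. Interferon-stimulated genes fell as a list, adjusted p = 0.00433, with 2 genes fallen and 0 risen, or 3 fallen when adjusted over the list alone. With an estimated correlation their adjusted p was 0.827. Their median was -0.184 in M-BMDM and -0.00502 in GM-BMDM. Ribosomal protein genes rose as a list (adjusted p = 0.0400, and 0.827 with an estimated correlation), with medians of 0.2 in M-BMDM and -0.0277 in GM-BMDM. Only these 2 of 34 lists passed with the preset correlation. With the estimated one 0 passed, but 1 residual degree of freedom left it little power.

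IL6 for 24 h went with a large difference in M-BMDM. Genes of DNA replication and cell division were higher, up to near the level in marrow for Rrm2. Replication-dependent histone genes did not share this rise: by the 2-fold limits 0 of 12 were higher and 4 lower (median log2 ratio -0.0379). Inflammatory mediators, interferon-stimulated genes, MHC class II and STAT3 target genes were lower. Of 10313 genes with at least 5 CPM, 1186 were at least 2-fold higher and 921 lower after 24 h of IL6. The labels give 7 days of culture for the untreated and the 24 h cells alike. Whether the 24 h of IL6 lay within these days is not known here, so the ages of the cells may differ. No library was labelled as kept for a further 24 h without IL6.

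Most of the genes with the highest ratios served replication, mitosis or their control. Cenpk (4.98) and Ska1 (4.44) belong to the kinetochore, Pole (4.82, 4.46 to 5.21) is a DNA polymerase, and Esco2 (4.54) joins sister chromatids. Dtl (4.32) directs the breakdown of replication factors, while E2f8 (4.32) and Tcf19 (4.34) are regulators of cell cycle genes. Pcyt1b, an enzyme of phosphatidylcholine synthesis (4.76), and Pask, a metabolic kinase (4.38), were among the 10 highest too. Of 34 proliferation genes, 33 were higher and 0 lower (median 2.77, against -0.2 to 0.229 for random lists), including Mcm7, of the replicative helicase (4.26, 4.05 to 4.47), Cdc6 (4.26), Rrm2 (4.10, 3.94 to 4.26) and Tyms (3.78). Mcm7 (chromosome 5, 138164583 to 138172422) had 321 CPM in BM, 10.7 in M-BMDM, 15.8 after 3 h and 205 after 24 h, and Rrm2 (chromosome 12, 24708241 to 24714146) had 336, 18.0, 21.7 and 309. The cholesterol exporter Abcg1 (3.15), Mertk (2.65), the progenitor antigen Cd34 (2.22) and the RNA sensor Tlr7 (1.40) were higher as well.

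Il1b, the cytokine interleukin-1 beta (chromosome 2, 129364570 to 129371139), had 260 CPM in M-BMDM, 246 after 3 h and 0.914 after 24 h, a log2 ratio of -8.15 (-8.83 to -7.55). Il1a, the related cytokine (-7.66), Olr1, a receptor for oxidised lipoprotein (-7.58), Cxcl3 (-7.26), Thbs1, thrombospondin (-6.72), Gng4 (-6.11), Acod1 (-5.74, -5.85 to -5.63), Fosl1 (-5.61) and the linker histone Hist1h1c (-5.60) were lower, and Rps13-ps2 was at least 148.3-fold lower. Pro-inflammatory genes were lower for 21 of 31 and higher for 0 (median -2.64), including Cd86, a costimulator (-3.99). STAT3 target genes were lower for 15 of 40 and higher for 0 (median -0.984, against -0.252 to 0.189 for random lists), including Il1rn, which blocks interleukin-1 (-3.96), Vegfa (-3.87), Tgm2 (-3.85) and Socs3 (-3.74, -3.97 to -3.52). Interferon-stimulated genes were lower for 19 of 39, with Cxcl10 (-4.29), Mx1 (-3.70) and the GTPase Gbp5 (-3.51), and MHC class II genes for 9 of 14, with H2-Ab1 (-2.64), H2-Eb1 (-2.40) and H2-Aa (-2.13). Matrix genes were lower for 13 of 27, with the proteases Mmp14 (-4.27) and Mmp13 (-3.52) and the urokinase receptor Plaur (-3.50). Glycolysis and hypoxia genes were lower for 9 of 26, with Slc2a1 (-2.86) and the hexokinase Hk2 (-2.38). Of 26 genes of IL6 family and growth factor signalling, 5 were lower and 2 higher. Besides Socs3 the lower ones were Csf1, which encodes M-CSF (-2.84), Osm, an IL6 family cytokine (-1.93), the kinase Jak2 (-1.84) and Csf2rb (-1.19). The higher ones, named after their values were seen, were Lifr, the receptor for leukaemia inhibitory factor (1.47), and Pias3, an inhibitor of STAT3 (1.33). Stat3 (-0.17), Il6ra (0.71), Il6st (0.32), Csf1r (-0.45) and Csf2ra (-0.29) were neither.

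In the test, 3557 genes rose and 3324 fell with IL6 at 24 h, or 4330 and 2467 with total counts, a median shift of 0.14. In either direction the DESeq2 test called 3617 genes and a fixed coefficient of variation of 0.2 called 2745. Rrm2 (4.05, standard error 0.118, adjusted p = 1.0e-129), Pclaf, a partner of PCNA (4.16, 0.127, 5.1e-123), and Mcm7 (4.10, 0.126, 1.4e-122) rose, as did Clspn, a checkpoint mediator (4.23), Uhrf1, which maintains DNA methylation (3.96), and Mcm5 (3.58). Il1b (-8.19, 0.2, 2.8e-158), Thbs1 (-6.73, 0.166, 3.6e-157), Acod1 (-5.72, 0.150, 2.9e-146) and Socs3 (-3.73, 0.149, 7.1e-88) fell. The cystine carrier Slc7a11 (-4.94), the fatty acid receptor Gpr84 (-4.65) and the lectin Clec4e (-3.87) fell too, while Stat3 was not called. All 34 proliferation genes rose, also when adjusted over the list alone (adjusted p = 2.3e-16 for the list, 0.663 with an estimated correlation). Of STAT3 target genes 3 rose and 27 fell, the same when adjusted over the list alone (adjusted p = 4.4e-07, and 0.663 with an estimated correlation). Pro-inflammatory genes had 1 rise and 25 falls (4.3e-10, 0.663), interferon-stimulated genes 1 and 30 (7.6e-08, 0.747), MHC class II genes 0 and 11 (9.2e-06, 0.663), and IL6 family and growth factor signalling genes 7 and 15 (0.0413, 0.747). Of 34 lists, 14 passed with the preset correlation and 0 with the estimated one. The estimated correlation rests on 1 residual degree of freedom, so the lists that failed with it are not thereby shown to be unchanged. The 24 h library is a lone one, so its spread was taken from the 3 h libraries.

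**Figure D3:**
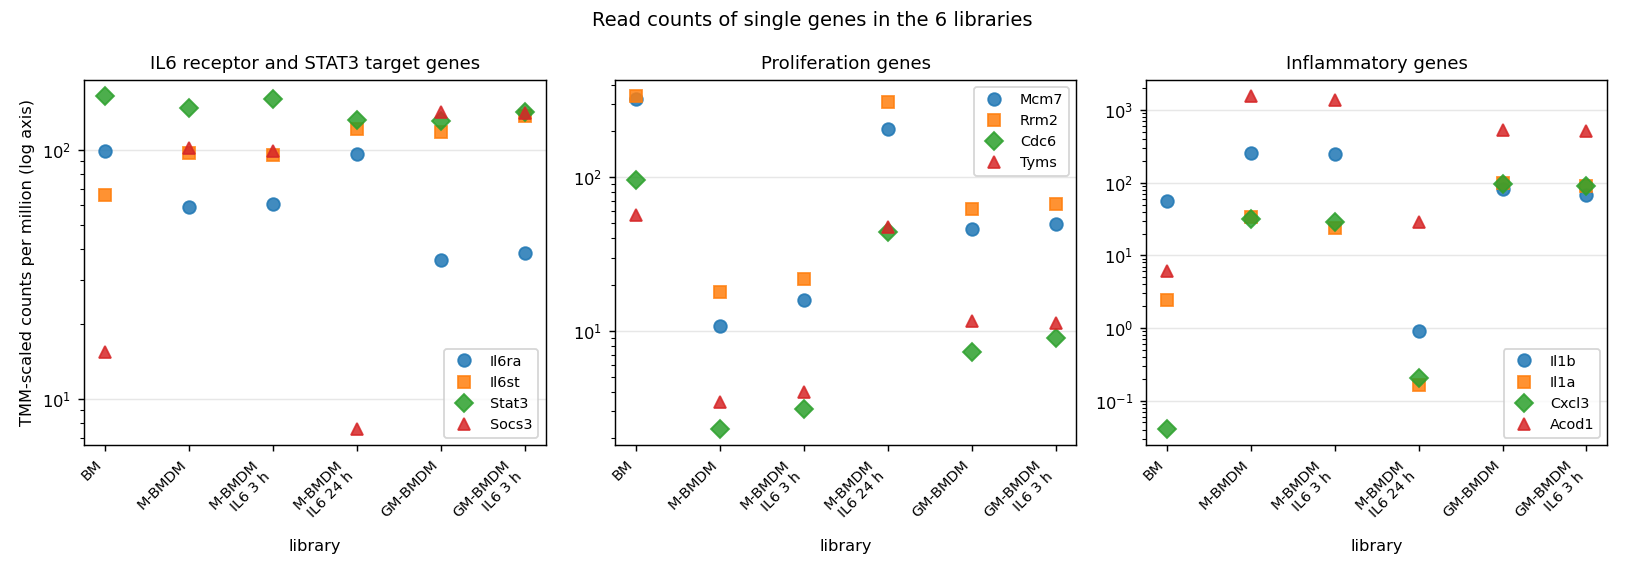
Scaled counts of single genes in the 6 libraries. Socs3 and Il1b were lower and Mcm7 and Rrm2 higher after 24 h of IL6.

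Genes that differed at 24 h mostly moved toward their level in marrow. To avoid a shared library, the 3 h library served as the reference for 24 h, a choice made after the data were seen. This removes only the counting error of a shared library. The 3 h and untreated libraries correlated at 0.989, so anything peculiar to both would still give overlaps in opposite directions. Of the 1204 genes then higher at 24 h, 731 were among the 2587 genes lower in M-BMDM than in BM (212 expected if independent), such as Mcm7 and Rrm2. Of the 883 genes then lower, 545 were among the 2260 genes higher in M-BMDM than in BM (136 expected), such as Acod1 and Socs3. Overlaps in the same direction were 83 (185 expected) and 69 (155 expected). The expected numbers of all overlaps given here were computed over all 14719 genes. These include genes too low to be called, so the expected numbers are too low. Against the untreated library, the 3 h and 24 h ratios in M-BMDM correlated at 0.145 with a covariance of 0.0382, against 0.514 and 0.0157 in simulations that shared only this library. They shared 2 genes higher (0.725 expected if independent) and 8 lower (1.69 expected), against 1 shared call in the simulations, and part of this excess may come from the shared library.

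No gene passed in the test of whether the IL6 response differed between GM-BMDM and M-BMDM. edgeR gave 0 genes with 31 below an unadjusted p of 0.05, DESeq2 gave 0 with 36, and limma-voom gave 0 with 157. That fit counted the difference between the 3 h and 24 h libraries of M-BMDM as spread, so it had little power to detect such a difference.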

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

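The genes in this paragraph were singled out after their values were seen, because their differences between the 3 h library and its control ran in opposite directions in the 2 macrophage types. Their ratios were computed with a prior count of 2. Rps27rt, a retrogene of a ribosomal protein, was lower in M-BMDM (log2 -1.06, 116 and 65 counts) and higher in GM-BMDM (1.08, 78 and 141 counts), a difference of 2.14. 2210418O10Rik was lower in M-BMDM (-1.08, 237 and 132 counts) and higher in GM-BMDM (1.63, 65 and 173), a difference of 2.71. Gm12537 was higher in M-BMDM (1.27, 41 and 120 counts) and lower in GM-BMDM (-1.12, 199 and 76), a difference of -2.39. Srp54c, a copy of the signal recognition particle gene Srp54a, had 0 and 136 counts in M-BMDM and 202 and 0 in GM-BMDM, so it was at least 38.28-fold higher and at least 56.68-fold lower. Its difference of -12.73 depends on the prior count and is no bound. Each of these differences was not tested, since no spread is left for a difference of the 3 h responses. Loci without a gene name held 0.522% of the counts in BM, more than in any culture, and were left out of the comparisons; this difference was not tested either.

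The first pattern weighed is the near absence of a response at 3 h, for which the tests of a repeated library and of absent receptors were chosen after the result was seen. The libraries were not copies of each other, since the median chi-square over counting error was 3.19 in the pair of GM-BMDM and 4.86 in that of M-BMDM, and receptor transcripts were present, with Il6ra in GM-BMDM the lowest at 36.3 CPM. Whether the IL6 was active and whether the 3 h and control libraries carry the right labels was not tested, so the 3 h values may not measure a response to IL6 at all. For a GC content trend between libraries, the limit set before its result was fewer than 50% of calls remaining. With the trend removed, 19.1% of the calls in the 4 libraries remained, which met that limit for a cause of the calls. The cause stays open here only through a condition outside that limit, that the changes also shrink below 50% of their size. The median log2 change of the calls fell from 0.473 to 0.404 at standard errors of 0.112 and 0.108. Only 4 of 136 calls lost over 50% of their size. The ratios followed GC content at 0.484 in M-BMDM and 0.165 in GM-BMDM. In the joint test, genes called lower had a median GC content of 41.1%, those called higher 51.6% and all tested genes 49.3%. Overlap with another gene, where reads could move between loci, was seen for 58.5% of called genes (95% interval 49.9 to 66.7) and 55.2% of others, which does not separate the cases.

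The next pattern is the 24 h difference in M-BMDM, for which the tests of marrow admixture and of STAT3 target genes were chosen after the result was seen. Scaling did not account for the proliferation genes, whose median was 2.91 with total counts and 2.77 with TMM. Uncultured marrow mixed into the library did not account for them either, since among the 10 most abundant erythroid and neutrophil genes of BM the one nearest its BM level, Lcn2, reached 0.0178% of it while 77.1% was needed. STAT3 target genes had a median of -0.984, which argues against a raised level of these transcripts at 24 h and says nothing about earlier times or other effects of IL6. Time in culture could not be separated from IL6, since 0 libraries were labelled as kept for the same 24 h without it. The labels give 7 days for the untreated and the 24 h cells, which leaves open whether their times in culture differed.

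Placental transcripts are the last pattern, and both of its tests and their limits were chosen after the result was seen. A list of trophoblast genes summed to 41.4 CPM in BM, 56.2 in GM-BMDM, 34.1 in GM-BMDM with IL6 for 3 h, 110 in M-BMDM, 49.1 with IL6 for 3 h and 71.7 with IL6 for 24 h. The lowest correlation of log2 counts between 2 libraries over 22 genes of the list was 0.856, against 0.191 at the 95th percentile of random lists. Carry-over from 1 placental source would give such a value. Any list whose genes kept their proportions between marrow and culture would give it too, so the test cannot tell carry-over from another steady source. BM reached 0.376 of the sum in M-BMDM, although BM had not been cultured, so the transcripts were not confined to cultured cells. This rests on 1 BM library and does not exclude some expression by cultured macrophages. Psg16, Tpbpa, Psg21 and Prl3b1 had 178, 100, 93 and 99 counts in BM and 180, 217, 216 and 207 in M-BMDM.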

How the results depend on the processing

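Of the total counts of genes or lists, 71 stayed within 1.5-fold of the reported total under the alternatives and 31 moved beyond that range. This range took no account of direction, and the balance of higher and lower genes turned over in several settings. For GM-BMDM against M-BMDM it was 904 higher and 1191 lower with total counts, and 3439 and 4912 in the test. At 24 h the test gave 3417 and 3477 with DESeq2 factors and 1753 and 1864 with the DESeq2 test, and M-BMDM against BM gave 1690 and 1666 at a minimum of 20 CPM. At 3 h the excess of falls ended with the fixed coefficient of variation (19 and 19). Total counts gave 1463 higher and 757 lower at 24 h, and for M-BMDM against BM 1911 and 3002, or 4127 and 6285 in the test, where DESeq2 called 7108. No single named gene changed direction; these were the same in 441 cases and weaker in 22, mostly 3 h genes under DESeq2. Csf2ra passed 2-fold in GM-BMDM against M-BMDM with DESeq2 factors (1.00). By construction, stricter or looser limits moved counts. A fold limit of 3 left 3206 genes for M-BMDM and 3058 for GM-BMDM against BM. For GM-BMDM against M-BMDM, minima of 1 and 20 CPM gave 3141 and 1318 genes, and fold limits of 1.5 and 3 gave 3966 and 1039. In the same order, IL6 at 3 h gave 285, 4, 166 and 10 genes in M-BMDM and 221, 1, 110 and 8 in GM-BMDM. At 24 h, fold limits of 1.5 and 3 gave 4027 and 1041.

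For the tests, DESeq2 called 6877 genes for GM-BMDM against BM, 4969 for GM-BMDM against M-BMDM, 3 at 3 h and 3617 at 24 h, where 1713 had no adjusted p. The fixed coefficient of variation, chosen after seeing the data, gave 4359 for the macrophage types, 38 at 3 h and 2745 at 24 h. With both IL6 times as 1 term, 650 genes differed between the types and 0 with IL6, and with cell type alone 1857 differed, since the 24 h difference then counted as spread. At 3 h, total counts gave 81 genes, 80 of them among the 142, and removal of the GC trend, also chosen after seeing the data, gave 27, of which 25 were. With an estimated correlation 0, 0 and 0 lists passed for 3 h, 24 h and the macrophage types. That setting rests on 1 residual degree of freedom, so few lists could pass it, whatever their genes did. Where no reason is given, the cause was not tested. With the 3 h library as reference, chosen after seeing the data, 2087 genes differed at 24 h, and 1048 of the 1186 higher and 786 of the 921 lower genes were shared. No paired analysis was possible because each group had 1 library and the labels carry no replicate numbers; the joint test sets each 3 h library against the control of its own cell type. Depth limits genes under 5 CPM, where counting intervals are wide.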

Other observations

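Some marker genes of cell types other than macrophages were higher in GM-BMDM than in M-BMDM, beside 1134 of 10495 among all genes with at least 5 CPM. Megakaryocyte and platelet genes were higher for 3, lower for 0 and neither for 12 of 15. Stem and progenitor genes were higher for 4, lower for 0 and neither for 15 of 19. Mature neutrophil genes were higher for 5, lower for 2 and neither for 18 of 25 genes, with Mmp8, a collagenase of neutrophils, at 5.74. Erythroid genes were higher for 1 and lower for 1 of 26, B lineage genes for 2 and 0 of 24, and T and NK cell genes for 0 and 0 of 20. Monocyte genes were higher for 8 and lower for 5 of 16. Ccl6, a chemokine of myeloid cells, was higher by 6.45. Nuclear genes of oxidative phosphorylation rose for 27 and fell for 2 of 32 in GM-BMDM against M-BMDM (adjusted p = 0.000410, and 0.587 with an estimated correlation).

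After 24 h of IL6, M-BMDM also had lower monocyte genes (5 of 16 lower, 0 higher). Genes of the immediate early and handling stress list were lower for 12 of 21 and higher for 1 (median log2 ratio -1.37). A difference in handling between the 2 libraries was not tested. Chemokines with their receptors were lower for 14 of 29 and higher for 1, with Ccl22 at -5.20. Sterol synthesis genes were lower for 7 of 24 and higher for 1. In the test, 11 monocyte genes fell and 0 rose (adjusted p = 7.0e-05, and 0.663 with an estimated correlation). Chemokine genes fell for 18 and rose for 3, or 19 and 3 when adjusted over the list alone (adjusted p = 4.5e-05, and 0.747 with an estimated correlation). Cebpb, a transcription factor of myeloid cells, was lower (-3.42), as was Cd14, which binds endotoxin (-1.51).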
